A study of Mus musculus with 12 samples.

How the data were processed

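The data are 6 peak lists from chromatin immunoprecipitation of MACF1 in MC3T3-E1 cells, 3 from control and 3 from MACF1 knockdown cells, each made against 1 of 6 input libraries. Per the labels' protocols, lysates were sonicated, incubated with an anti-MACF1 antibody and captured on magnetic beads, and libraries were made with a ligation kit and size-selected on gels. The labels list more than 1 antibody lot without assigning lots to libraries. What the label size3 stands for is not given in the sources used here.

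Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with Bowtie2 to GRCm38. Per the file headers, peaks were called with MACS 1.4.2 on uniquely mapped reads for each immunoprecipitate against its own input, without pooling, at a p cutoff of 1.00e-05, a band width of 300 bp and 1 read kept per position. The deposited read counts per peak are whole numbers of reads in the peak after duplicate removal. The deposited score of each peak is 10 times the negative log10 of the p-value against the local background of the input. The deposited fold enrichment is a ratio of reads at the summit to that background. The deposited false discovery rate, in percent, is the share of peaks found at the same or a better p-value with the immunoprecipitate and input swapped. The deposited peak width and summit position are in bp. A score or fold belongs to its peak and was used only to describe, rank or filter peaks within a list.

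The headers give the reads after duplicate removal: 26196138, 33085606 and 10698067 in control 1, 2 and size3 and 18454330, 5575205 and 8175173 in knockdown 1, 2 and size3 immunoprecipitates. Their inputs held 27114349, 26467245 and 10529079 and 27126451, 28266305 and 10199730. The redundant rate of the immunoprecipitates was 0.25, 0.16 and 0.01 in control and 0.51, 0.65 and 0.02 in knockdown libraries. Wilson intervals cover counting error only. Peak calls depend on depth, input and duplicates, so peak numbers are given beside these values. Groups and replicate labels came from the sample labels.

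Peak numbers, covered bp and shares of summits were compared between 3 and 3 libraries by exact two-sided permutation over 20 assignments, the first 2 on the log2 scale. Lists were compared by overlap of at least 1 bp, against 1000 random placements of the shorter list within the same chromosomes (200 for alternatives), with two-sided p-values adjusted by the Benjamini-Hochberg method. The 1000 placements give no p under 0.002. All lists were merged into 44202 regions where they touched, of which 94.9% came from 1 library, and a consensus region was called in at least 2 of the 3 libraries of a group. Local shifts moved each peak by 50 kb to 1 Mb on chromosomes 1 to 19, X and Y.

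Gene spans came from the RefSeq gene table of GRCm38.p6, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table used here gives no strand or exons, so the planned share at transcription starts was replaced by the share within 1 kb of either gene end, with the share inside genes as an unplanned companion. This substitute was settled after both shares had been seen. Exons, introns and GC content were not analysed here. Of 444 entries of the 10 gene lists, 442 matched a gene. Members with a consensus region in the body or within 5 kb were counted against 10000 random lists matched on gene length in 20 bins, with adjustment over 10 lists and both groups. The named genes were, by rule, Macf1, the 10 consensus regions of each group with the best mean rank of fold enrichment, at most 4 members of each list and group by number of libraries with a peak and then by best fold, and up to 10 regions called in all libraries of one group and in none of the other. A region outside genes was named by the nearest gene, since no transcription start was known. Some items that the rule names are not reported here.

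The steps were tested on simulated data. Independent lists with the lengths and widths of knockdown 1 and knockdown size3 gave a ratio to chance of 0.991, and 1000 planted shared sites gave a mean excess of 974. Both simulations placed peaks uniformly, as the random placements do. They check the calculation and do not show how it behaves for peaks that gather at genes. For lists of 60 genes, 3.33% with no effect, 56.3% with 2 times and 96.3% with 3 times the hit rate had an unadjusted p under 0.05. The comparisons, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined, except that the sizes of the lists were already known and showed longer knockdown lists, so the comparisons of peak number and cover were planned with their direction seen. These alternatives covered stricter peaks, equal list lengths, other overlaps, other consensus rules, other chromosomes, the replicate label as a block, the median, peaks per unit of reads and each library left out. Alternatives chosen after seeing the data were local shifts, windows of 3 kb, gene ends only, the nearest gene end, matching on gene density and single labels. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.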

Results

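Chromatin immunoprecipitation with an antibody against MACF1 was followed by sequencing in MC3T3-E1, a mouse osteoblast line. MACF1 is a large protein that links actin filaments to microtubules and acts in Wnt signalling. Cells with MACF1 knockdown were set against control cells, to ask where in the genome the antibody recovered DNA under each condition. The 12 samples formed 4 groups of 3: control and knockdown immunoprecipitates and their matched inputs. Libraries carried the labels 1, 2 and size3 in each group. Each of the 6 immunoprecipitates had its own peak list, called against its own input. The control immunoprecipitates held 26196138, 33085606 and 10698067 reads after duplicate removal for labels 1, 2 and size3. The knockdown immunoprecipitates held 18454330, 5575205 and 8175173. The labels do not state that libraries came from separate cultures, so p-values between groups measure only the spread between these libraries.

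The knockdown libraries had longer peak lists than the control libraries. The control lists held 772, 198 and 2196 peaks for labels 1, 2 and size3, and the knockdown lists held 21398, 4513 and 17592. The difference of mean log2 peak number was 4.10, a 17.2-fold difference of geometric means, with no overlap between groups (exact two-sided permutation p = 0.1, n = 3 against 3, the smallest p that 20 assignments allow). Peaks covered 0.781 Mb ± 0.652 (SD, n = 3) in control and 15.3 Mb ± 14.5 (SD, n = 3) in knockdown libraries, a 15.0-fold difference of geometric means (exact permutation p = 0.1). The size3 libraries had a redundant rate of 0.01 to 0.02 in all 4 groups and the others one of 0.16 to 0.65, so values within a label are given: the fold in peak number was 27.7 for label 1, 22.8 for label 2 and 8.01 for size3, and the fold in cover was 48.8, 7.62 and 9.03. The peak caller's false discovery rate, obtained by swapping the immunoprecipitate and its input, divided the lists differently. Peaks with a rate of at most 5% numbered 21159 in knockdown 1, 10161 in knockdown size3, 51 in knockdown 2 and 1, 0 and 0 in control 1, 2 and size3. In control 1, control 2 and knockdown 2, 99.7%, 100% and 98.4% of peaks had a rate of 100%.

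**Figure D1:**
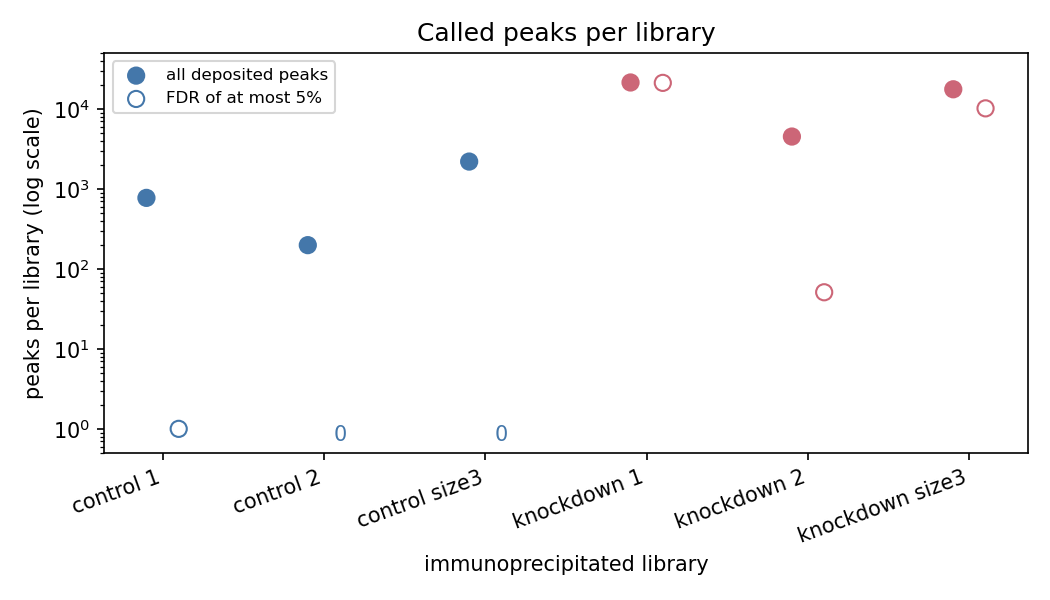
Number of peaks per immunoprecipitated library on a log scale, with filled points for all deposited peaks and open points for those with a false discovery rate of at most 5% (0 is written where none remained). Blue is control and red is knockdown; all 3 knockdown lists lie above the control lists of 198 to 2196 peaks, and only knockdown 1 and knockdown size3 keep over 10000 peaks at the stricter threshold.

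The authors' peak caller described the shape of the peaks in each list. Median peak width was 732 bp, 936 bp and 650 bp in control 1, 2 and size3, and 990 bp, 359 bp and 647 bp in knockdown 1, 2 and size3. Median fold enrichment over input was 4.98 in knockdown 1, 8.10 in knockdown size3 and 15.6 in knockdown 2, where a median peak held 9 reads. It was 5.35, 6.36 and 8.33 in control 1, 2 and size3. These medians describe each list and no difference between libraries was tested.

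Macf1, the targeted gene (chromosome 4, 123349633 to 123687802, GRCm38), had no peak in the gene or within 5 kb in the 3 control libraries. Knockdown 1 had 1 peak there, at 123685611 to 123688035, across the upper end of the gene, with a fold enrichment of 3.96 and 138 reads. Knockdown size3 had 1 peak inside the gene at 123664307 to 123665523, with a fold enrichment of 5.90 and 29 reads. Knockdown 2 had none. These peaks lay apart from each other. A binding assay of genomic DNA does not measure Macf1 expression, so neither the knockdown nor the group labels were checked here.

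Which libraries shared peaks did not follow the groups. Of the 17592 peaks of knockdown size3, 2034 (11.6%) overlapped a peak of knockdown 1, against 373 under random placement, a ratio of 5.46. The other 2 pairs of knockdown libraries shared fewer peaks than chance: 44 against 75.1 for knockdown 2 with knockdown 1, and 24 against 43.9 for knockdown 2 with knockdown size3. Knockdown 2, with 4513 peaks, overlapped instead with 74 of the 198 peaks of control 2 (chance 16.4) and 77 of the 772 peaks of control 1 (chance 15.0). With control size3 it shared 7 peaks (chance 5.38, permutation p = 0.6). Control 1 and control 2 shared 72 peaks (chance 15.3), while control size3 shared 1 with each of them. Control size3 shared 105 of its 2196 peaks with knockdown 1 (chance 47.0) and 74 with knockdown size3 (chance 28.7). None of the peaks of control 1 overlapped one of knockdown 1, against 16.4 by chance. All of these pairs except control size3 with control 1, control 2 and knockdown 2 had a permutation p of 0.002, the smallest that 1000 placements can give. Their Benjamini-Hochberg adjusted p was 0.0033 over 15 pairs. The mean log2 ratio to chance was 0.66 higher within than between groups, but -0.32 without knockdown 1 and -0.07 without control 1. Against peaks moved by 50 kb to 1 Mb, an alternative chosen after seeing the data that keeps the neighbourhood of each peak, the overlap of knockdown size3 with knockdown 1 was 3.10 times chance, and that of control size3 was 1.48 times with knockdown 1 and 1.70 times with knockdown size3. The ratio was 163 for control 2 with control 1, 78.0 for control 2 with knockdown 2 and 18.4 for control 1 with knockdown 2. Under shifts, which leave out unplaced sequence, these pairs shared 48, 48 and 53 peaks. Their chance means were 0.3, 0.62 and 2.88, so the first 2 ratios rest on very small numbers. Without unplaced sequence and recurrent regions these pairs shared 33, 31 and 32 peaks.

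**Figure D2:**
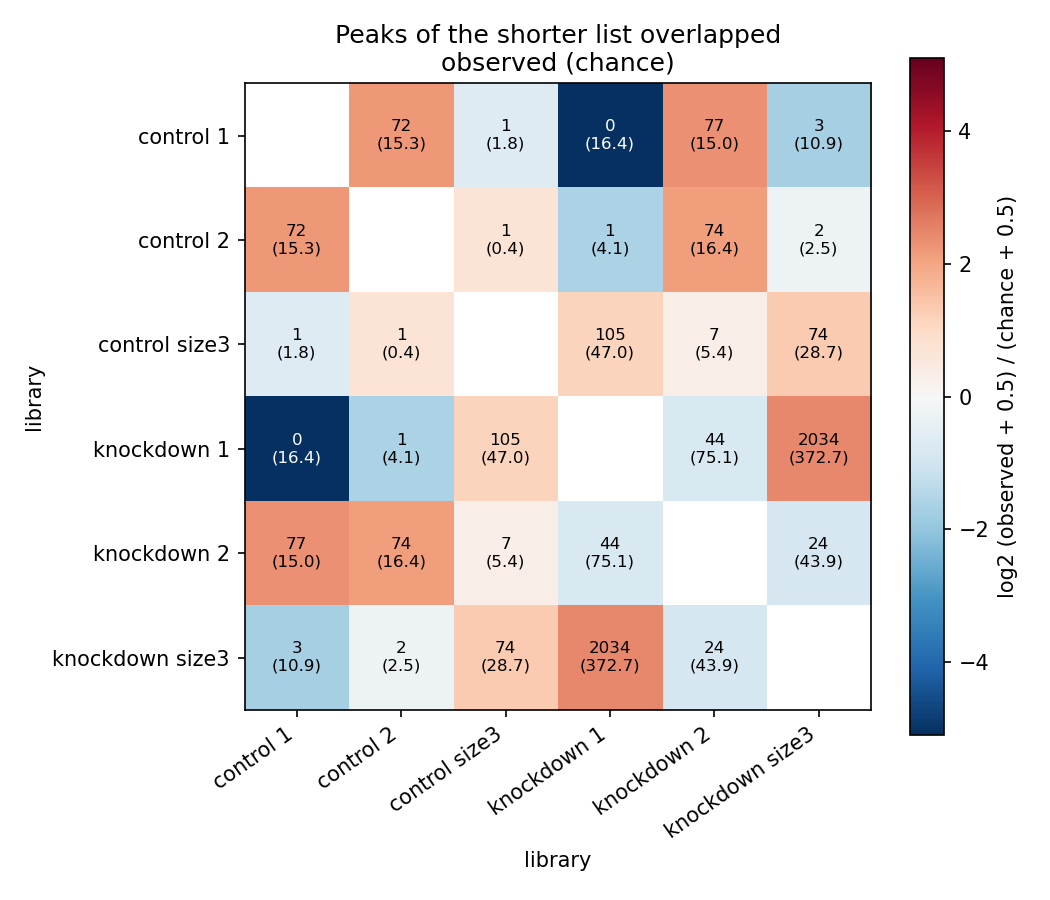
Overlap of peak lists for each pair of libraries, with the number of peaks of the shorter list overlapped by the longer and, in brackets, the mean of 1000 random placements. Colour gives the log2 ratio of the observed to the chance number with 0.5 added to each; red cells join knockdown 1 to knockdown size3 and join control 1, control 2 and knockdown 2, and paler red cells join control size3 to knockdown 1 and to knockdown size3.

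Regions called in at least 2 libraries of a group, termed consensus regions, numbered 2010 in knockdown, against 478 under random placement and 718 under local shifts. Of these, 1929 (96.0%) were shared by knockdown 1 and knockdown size3 and by no other library. The count was 24 without knockdown 1, 43 without knockdown size3 and 1954 without knockdown 2. A control peak overlapped 19 knockdown consensus regions (3.61 by random placement and 7.19 by local shifts), in each case a peak of control size3; without that library the number was 0. The regions with the best mean rank of fold enrichment lay inside genes with varied functions or between genes. A region in Mdm2, which encodes a ubiquitin ligase for p53 (chromosome 10, 117704294 to 117704813), had a fold enrichment of 8.72 in knockdown 1 and 14 in knockdown size3. In Asic2, an acid-sensing ion channel gene on chromosome 11, the region at 81085963 to 81086519 was called in knockdown 1 and knockdown size3 and that at 81301916 to 81302539 in knockdown 1 and knockdown 2. Cadps, a gene of vesicle exocytosis on chromosome 14, also held 2 of these regions, at 12540980 to 12541604 and at 12648508 to 12648976. A further 4 lay between genes, nearest to Olfr267 (chromosome 4, 58701243 to 58701986), Gm40624 (chromosome 10, 38302651 to 38303197), Gm17019 (chromosome 5, 15010947 to 15011573) and Fam135b (chromosome 15, 71029854 to 71030527). Their distances to these genes were 82793, 51587, 17377 and 408424 bp, in that order. Ranks were not scaled to list length, which favours the shorter list of knockdown 2. The regions near Olfr267 and Gm17019, at 81301916 in Asic2 and at 12648508 in Cadps were called in knockdown 2. Their false discovery rate there was 100%.

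Control consensus regions numbered 73, against 12.2 under random placement and 2.87 under local shifts, and 71 of them were called in both control 1 and control 2 or in those libraries and knockdown 2. Control regions outnumbered knockdown regions at equal list lengths (67 against 8) and without knockdown 1 or knockdown size3 (73 against 24 or 43). Knockdown peaks overlapped 62 of the 73, in each case a peak of knockdown 2. The count fell to 1 without control 1 and to 1 without control 2, and without knockdown 2 none of the 73 had a knockdown peak. Unplaced scaffolds held 22 of the regions, the mitochondrial genome 2, and a fixed list of 6 satellite and multicopy regions held 16, together 54.8% (95% Wilson interval 43.4 to 65.7). The same sequence held 0.0995% of the knockdown consensus regions. The highest-ranked control region lay in Chl1, a neural adhesion gene (chromosome 6, 103648882 to 103649771), with a fold enrichment of 21.9 in control 1, 23.2 in control 2 and 167 in knockdown 2. Emp2, a membrane protein gene on chromosome 16, held regions at 10283972 to 10286100 and 10287548 to 10288585, the first with a fold enrichment of 39.6 in control 1, 21.3 in control 2 and 23.3 in knockdown 2. Further regions lay in Gm52725 (chromosome 4, 28176456 to 28177507) and Cldn34d (chromosome X, 76598420 to 76599514), and nearest to Pak3 (chromosome X, 143482786 to 143483307), Dpy19l2 (chromosome 9, 24541526 to 24542663), 1700020D14Rik (chromosome Y, 258145 to 259671), Fam171a1 (chromosome 2, 3049941 to 3050853) and Gm30417 (chromosome 5, 15637599 to 15639040). The distances from Pak3 to Gm30417 were 35059, 14384, 50356, 63371 and 3489 bp, in that order. All 10 top-ranked control regions were also called in knockdown 2. Their false discovery rate was 100% in control 1 and control 2, except for 50% at the first Emp2 region in control 1. In knockdown 2 it was 0.0% at Chl1 and 100% at both Emp2 regions.

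Regions called in all 3 knockdown libraries and in no control library numbered 7, and no region was called in all 3 control libraries. Inside genes, they lay in Pacsin1 (chromosome 17, 27704046 to 27712210), Prrt4 (chromosome 6, 29175906 to 29180773) and Rims2, a gene of the presynaptic active zone (chromosome 15, 39196765 to 39199451). Between genes, they lay nearest to Lrig3 (chromosome 10, 126040697 to 126042331), Zfp365 (chromosome 10, 67920402 to 67921305) and Pdia4 (chromosome 6, 47777678 to 47778829). The last lay in the ribosomal repeat region of chromosome 17 (39842850 to 39847253), with 6218, 2321 and 2956 reads in knockdown 1, 2 and size3 and fold enrichments of 1.52, 2.67 and 2.12. The split of the libraries into control 1, control 2 and knockdown 2 against the others gave 79 such regions over both sides. Of these, 61 were called in control 1, control 2 and knockdown 2, and 18 in control size3, knockdown 1 and knockdown size3.

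Peaks of 2 knockdown libraries, and to a lesser degree those of control size3, gathered at the ends of genes. Summits lay within 1 kb of either end of a protein-coding gene for 15.7% of peaks in knockdown 1 (95% Wilson interval 15.3 to 16.2) and 13.0% in knockdown size3 (12.5 to 13.5), against 3.19% and 3.21% under random placement and 4.68% and 4.73% under local shifts. The share was 1.60% in knockdown 2 (1.27 to 2.01), under the 3.05% of random placement and the 2.96% of local shifts. In control 1, 2 and size3 it was 2.83%, 0.0% and 5.51%, against 3.14%, 3.08% and 3.27%, with an upper limit of 2.28% for control 2. Local shifts gave 2.33%, 2.56% and 4.12% in these control libraries, with a permutation p of 0.42, 0.02 and 0.01. Against random placement the adjusted permutation p was 0.003 for control size3 and the 3 knockdown libraries, 0.019 for control 2 and 0.73 for control 1. The difference between groups was within the spread of the libraries: 10.1% ± 7.49 (SD, n = 3) in knockdown and 2.78% ± 2.76 (SD, n = 3) in control (exact two-sided permutation p = 0.3). Inside protein-coding genes lay 61.8% of summits in knockdown 1 and 59.6% in knockdown size3, against 40.7% and 40.9% under random placement, 50.0% and 50.3% under shifts of up to 1 Mb and 52.9% and 53.0% under shifts of up to 200 kb. The share was 40.8% in knockdown 2, against 40.2%, 41% and 42.1% for the same backgrounds. Control size3 had 51.8%, against 42.1% under random placement (adjusted permutation p = 0.004), 49.4% under shifts of up to 1 Mb (permutation p = 0.01) and 51.2% under shifts of up to 200 kb. Control 1 had 43.7%, against 41.9% under random placement (adjusted permutation p = 0.48), 40.4% under shifts of up to 1 Mb (permutation p = 0.03) and 39.9% under shifts of up to 200 kb. Control 2 had 39.4%, against 41.8%, 43.0% and 38.7% (adjusted permutation p = 0.6 for random placement and permutation p = 0.43 for shifts of up to 1 Mb). Group means were 54.1% ± 11.6 (SD, n = 3) in knockdown and 45% ± 6.31 (SD, n = 3) in control (exact permutation p = 0.3). In the size3 pair alone the knockdown share exceeded the control share by 7.44 points at gene ends and by 7.82 points in gene bodies.

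**Figure D3:**
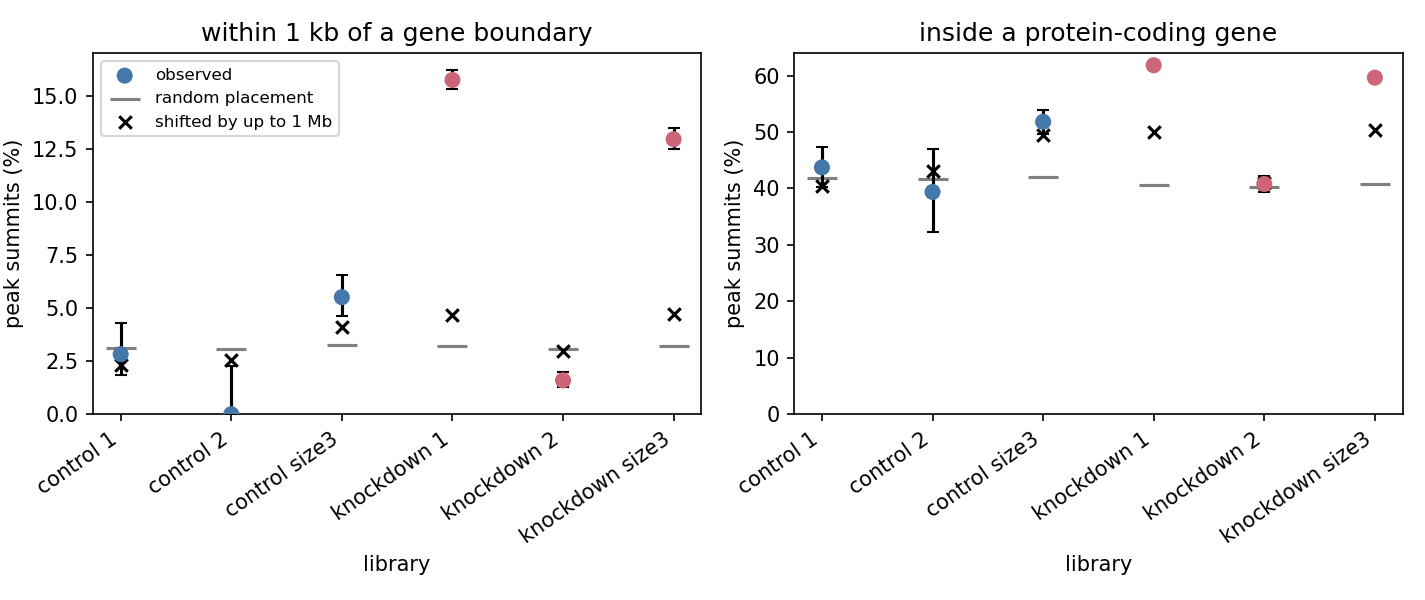
Percent of peak summits within 1 kb of either end of a protein-coding gene (left) and inside a protein-coding gene (right) for each library, blue for control and red for knockdown, with 95% Wilson intervals. Grey bars give random placement and crosses peaks moved by 50 kb to 1 Mb. At gene ends, knockdown 1 at 15.7%, knockdown size3 at 13.0% and control size3 at 5.51% lie above both.

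Genes with a knockdown consensus region in the body or within 5 kb numbered 1865 of 21887 protein-coding genes. None of the 10 gene lists held more or fewer of them than length-matched random lists after adjustment. Over both groups, 1 of the 20 tests had an unadjusted permutation p under 0.05. Among genes of osteoblast differentiation, 6 of 53 had a region (5.05 expected, permutation p = 0.77, adjusted p = 1.0). They included Runx2, the master transcription factor of the osteoblast lineage, with a region inside the gene at chromosome 17, 44776668 to 44777863, and a fold enrichment of 3.27 in knockdown 1 and 11.6 in knockdown size3. Dlx3, a homeobox gene, had one at chromosome 11, 95121249 to 95122441, and Cdh2, which encodes N-cadherin, and the matrix gene Tnc had one each. A control library also had a peak in or within 5 kb of Runx2 and of Tnc, outside these regions. In the Wnt pathway, 15 of 97 genes had a region (10.2 expected, permutation p = 0.16, adjusted p = 0.84). The region at one end of Ctnnb1, which encodes beta-catenin (chromosome 9, 120932802 to 120934623), had a fold enrichment of 3.43 in knockdown 1 and 12.6 in knockdown size3. Axin1, a component of the beta-catenin destruction complex, had one in its flank (chromosome 17, 26123177 to 26127700), and Wnt8b and Lgr6 had one each inside the gene.

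Of the cytoskeletal crosslinkers and microtubule plus-end genes, 12 of 50 had a region, against 6.08 expected, with a permutation p of 0.028 that did not pass adjustment over lists and groups (adjusted p = 0.56). Members were Dst, the closest relative of Macf1 (chromosome 1, 34127626 to 34128784), Clip1, a microtubule plus-end protein gene (chromosome 5, 123683161 to 123685337), the spectrin gene Sptbn1 (chromosome 11, 30266657 to 30268891) and Map1a (chromosome 2, 121288775 to 121290467), where control size3 also had a peak. Clip1 had a peak in 1 control library outside this region. The BMP, TGF-beta and Notch list had 8 of 56 genes (6.20 expected, adjusted permutation p = 1.0), among them the receptor genes Acvr1 and Bmpr1b, Notch3 and the BMP antagonist gene Nog. The list of E2F and class 1 helix-loop-helix factors and their partners had 5 of 26 (2.69 expected, adjusted permutation p = 0.84), including E2f5, Rnf2, Pcgf6 and L3mbtl2. Cell cycle genes had 2 of 40 (3.21 expected, adjusted permutation p = 1.0), the cyclin-dependent kinase inhibitor genes Cdkn2c and Cdkn1c. Among lists of other cell types, adipocyte genes had 5 of 23 (2.12 expected, adjusted permutation p = 0.84), including Cebpd, Prdm16, Cfd and Slc2a4. Neuronal adhesion and synapse genes, which are long, had 9 of 57 (11.3 expected, adjusted permutation p = 1.0), including Cdh18, Kcnip4 and Cntn6. Control libraries also had peaks in or within 5 kb of Bmpr1b and Lgr6, outside the named regions, and control size3 had one at the region of Pcgf6. Chondrocyte genes and osteoclast and macrophage genes had 0 of 20 each (2.0 and 2.02 expected, adjusted permutation p = 0.84 for both). A control consensus region lay at 14 genes, none of them in a list (adjusted permutation p = 1.0 for each list). Only 0.013 to 0.346 members were expected per list, so these tests could not have found fewer members than expected. With 3 libraries per group and no test per gene, a named gene is an example, not a call.

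Peaks were spread unevenly over chromosomes. Control 1 had 1.27 peaks per Mb on chromosome 19, 1.23 on chromosome 6 and 0.817 on chromosome 5, but 0.0138 on chromosome 7. Control size3 had 2.71 on chromosome 19, 2.37 on chromosome 5 and 0.262 on chromosome 7. Knockdown 1 had 13.0 peaks per Mb on chromosome 11, 10.2 on chromosome 7 and 1.44 on chromosome X, and knockdown size3 had 12.2, 7.0 and 0.486. Over the 19 autosomes, peaks per Mb followed the density of protein-coding genes in knockdown 1 (Spearman rho 0.818, permutation p = 0.001, adjusted p = 0.0035 over 21 relations). The rho was 0.511 in knockdown size3 (adjusted p = 0.035), 0.189 in knockdown 2 (adjusted p = 0.43) and 0.30, 0.352 and 0.421 in control 1, 2 and size3 (adjusted p = 0.25, 0.14 and 0.10). These correlations are across chromosomes, which are not independent replicates.

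**Figure D4:**
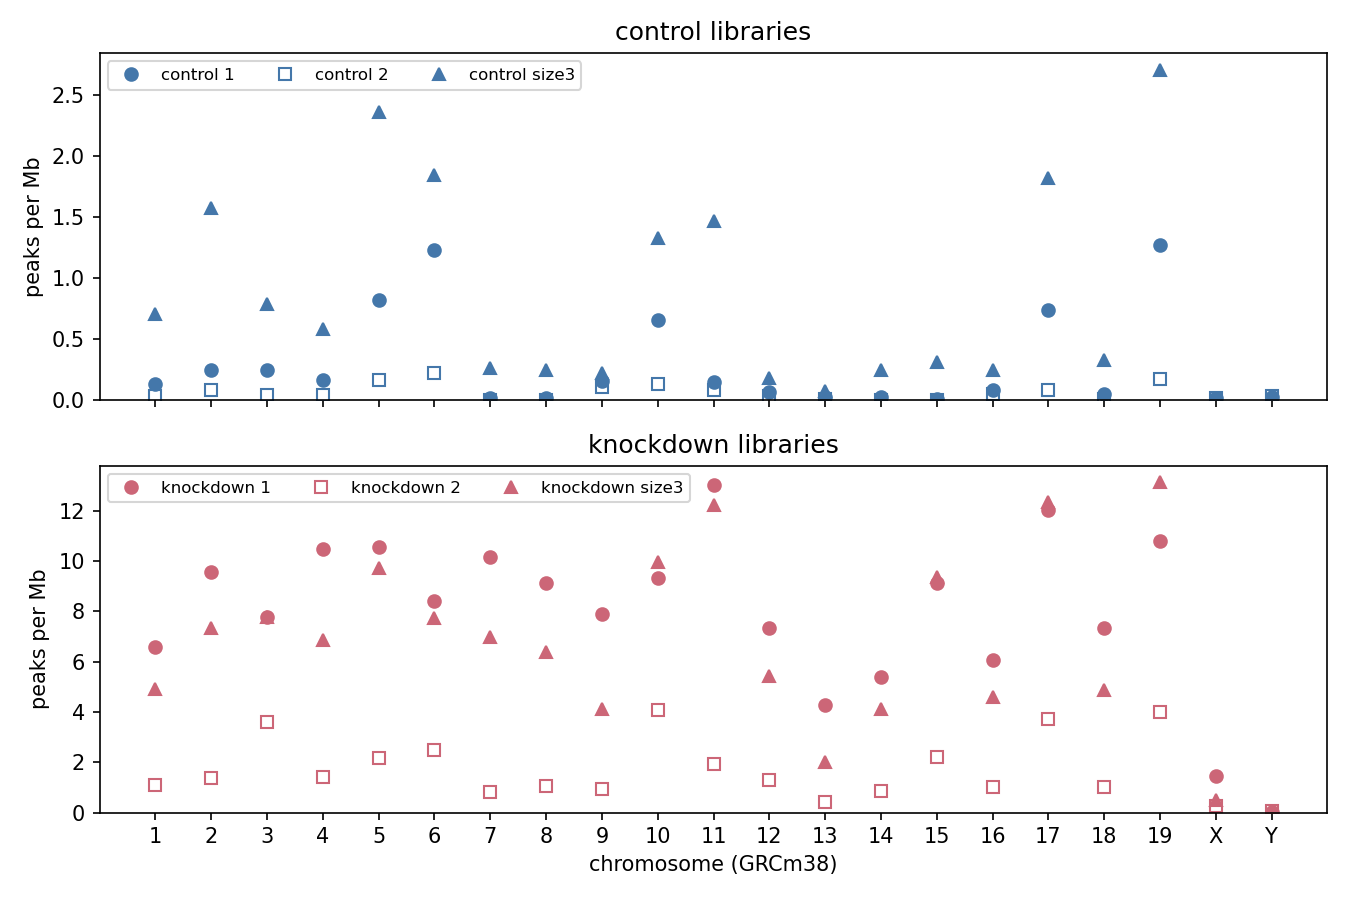
Peaks per Mb on each chromosome of GRCm38 in the control libraries (top) and the knockdown libraries (bottom), with circles for label 1, squares for label 2 and triangles for size3. The vertical scales differ; control 1 has 1.23 peaks per Mb on chromosome 6 and 0.0138 on chromosome 7.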

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

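The local shifts, the window of 3 kb, the gene end rules, the density matching, the single labels and all alternatives of the gene body share were chosen after seeing the data. Of 181 alternative values of the main results, 129 kept their direction and stayed within the limits set for them, 50 counts moved by more than 1.5 times and 2 differences changed sign. With 3 libraries per group no alternative could pass a p of 0.05 for peak number, cover or gene shares, so these values show direction only. The differences stayed positive under every alternative run for them. Leaving out each library gave 3.20 to 4.93 for log2 peak number, 3.01 to 5.11 for log2 cover, 4.49 to 11.6 points at gene ends and 5.24 to 15.8 points in gene bodies. Under the other alternatives they ranged from 3.0 (size3 alone) to 5.26 (peaks per unit of reads) for log2 peak number, from 3.18 to 4.43 for log2 cover, from 7.26 to 23.1 points at gene ends (equal list lengths, with 14.5 at a score of at least 100) and from 7.25 to 19 points in gene bodies (score of at least 100). At a false discovery rate of at most 5% the control libraries kept 1, 0 and 0 peaks, so the log2 difference in peak number, 10.8 with a pseudocount of 1, depends on that pseudocount. The replicate block gave the same difference of 4.10 in log2 peak number with an exact permutation p of 0.25, the smallest that 3 pairs allow, and changed no call. Correlations of deviations within labels 1, 2 and size3 were 0.00875, -0.124 and -0.0166. They cannot exclude pairing: label 2 libraries shared 74 peaks (chance 16.4) and size3 ones a low redundant rate.

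The counts of regions depended on the processing, in part by construction, since stricter lists and rules leave fewer peaks; otherwise the cause was not tested. Consensus regions, knockdown then control, numbered 58 and 35 at a score of at least 100. They numbered 1144 and 0 at a false discovery rate of at most 5%, and 7 and 0 in all 3 libraries. At least 1 library gave 41380 and 3088. The order reversed at equal list lengths (8 and 67) and with labels 1 and 2 only (43 and 71). Knockdown regions numbered 997 at a reciprocal overlap of 50% and 992 for summits within 250 bp. Control ones numbered 33 on assembled chromosomes without recurrent regions. Knockdown regions with a control peak numbered 0 at either threshold, at equal lengths, in all 3 libraries and with labels 1 and 2, 3 under both other overlap rules and 264 for at least 1 library. Control regions with a knockdown peak numbered 27 at the score threshold, 0 at the false discovery rate threshold and in all 3 libraries, 40 at the reciprocal overlap, 264 for at least 1 library and 25 on assembled chromosomes. Regions in all knockdown and no control libraries numbered 1 at the score threshold and for summits, 0 at the false discovery rate threshold and at equal lengths, and 3 at the reciprocal overlap. Leaving out each library gave 24 to 2010 knockdown and 1 to 73 control consensus regions, 0 to 19 and 0 to 62 of them shared with the other group, 7 to 1936 and 0 to 10 regions in all libraries of one group only, and -0.32 to 2.24 for the overlap within minus between groups, which was -0.07 without control 1 and -0.32 without knockdown 1. For gene lists, 1 knockdown list passed without length matching, the cytoskeletal one (Fisher's exact test, adjusted p = 0.016, with 0.016 to 1.0 over its alternatives), and with regions of at least 1 library 1 knockdown list, the Wnt pathway, and 1 control list, neuronal adhesion, passed (adjusted permutation p = 0.026 each, with 0.026 to 1.0 over the alternatives of each). The promoter and nearest transcription start alternatives were not run as planned because strand was not known; windows around gene ends took their place, and cover and gene shares gave no value at the false discovery rate threshold because control 2 and control size3 had no peaks left.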

Other observations

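The tests of depth, duplicates, multicopy sequence, gene density and copy number were chosen after the result was seen; the counts over splits were planned, with what they would show written afterwards. The longer knockdown lists were weighed first. Depth after duplicate removal argues the other way. The knockdown immunoprecipitate then had fewer reads than the control of the same label in all 3 pairs, with a ratio of at most 0.764. Before duplicate removal, knockdown 1 had more reads than control 1 (37841160 against 34806059). Knockdown 2 and knockdown size3 had fewer than their controls before removal too. Duplicate reads cannot account for the size3 pair, where both redundant rates were at most 0.02 and the fold was 8.01. For labels 1 and 2, where the fold was at least 22.8 and duplicates were more frequent in knockdown, the effects of duplicates and knockdown cannot be told apart. Open and untested are the balance of immunoprecipitate and input reads, the quality of each immunoprecipitation, the antibody lots, GC content, an exchange of group labels and the knockdown itself.

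The regions shared by control 1, control 2 and knockdown 2 may come from sequence that is present in more copies than the reference holds. Unplaced scaffolds, the mitochondrial genome and listed recurrent regions held 54.8% of control consensus regions, against 0.131% of regions called in 1 library (95% Wilson interval 0.101 to 0.171). Of the 41936 regions called in 1 library, however, 39123 came from a knockdown library. Unplaced and mitochondrial sequence held 3.76%, 16.7% and 1.37% of all peaks in control 1, control 2 and knockdown 2. It held 0.0%, 0.028% and 0.011% in control size3, knockdown 1 and knockdown size3. Part of the contrast therefore lies between libraries. Regions called only in control 1, control 2 or knockdown 2 were not compared apart. For the remaining 33 control consensus regions, copy number could not be examined without the genome sequence. No biological explanation was tested for this pattern.

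The uneven chromosomes of the control libraries were not set by gene density alone. Chromosome 7, with the most protein-coding genes per Mb, held 9.82% of autosomal protein-coding genes but 1.29% of the control peaks (95% Wilson interval 0.951 to 1.76). By library the share was 0.271%, 0.0% and 1.73% in control 1, 2 and size3. The 3 knockdown libraries together held 6.07% there (5.85 to 6.3), also under the share of genes. A candidate explanation is a different copy number of chromosomes in the line. The Spearman rho over autosomes was positive in the 15 pairs of libraries, lowest at 0.457 for control 2 with knockdown 1 (adjusted permutation p = 0.065), and that pair and control 1 with knockdown 1 (adjusted p = 0.064) did not pass adjustment. Copy number cannot be told apart from other chromosome-wide differences without read coverage of the inputs.

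The 10 splits of the 6 libraries are too few for a share under 0.05. For overlap within minus between groups, the real value was 0.66, the highest other 3.04, and 2 of 10 splits were as large. For regions in all libraries of one side only, the real value was 7, the highest other 79, and 2 of 10 splits were as large. The split with 79 put control 1, control 2 and knockdown 2 together, with 61 regions on that side and 18 on the other. Sharing of regions thus did not follow the groups. Unplaced, mitochondrial or listed recurrent sequence held 37 of the 62 control consensus regions with a knockdown peak. The splits were not counted without that sequence, so a structure of the samples cannot be told apart from its effect.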
